A study of Mus musculus with 13 samples.

How the data were processed

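Gene expression was measured in S1 proximal tubule segments of male C57BL/6J mice in 3 groups: saline controls, mice given 1 dose of lipopolysaccharide (LPS), and mice given a small dose before the same challenge (LPS/LPS). Per the labels' protocols, RNA was extracted with the PicoPure kit, concentrated by isopropanol precipitation, and 2 ng per sample was labelled with biotin by the Affymetrix WT Pico method. The authors deposited log2 expression values per probe set, and the submitters' processing notes name RMA (robust multi-array averaging) and Partek 6.6. RMA summarises the probes of a probe set into 1 log2 value, and any background signal left in it would compress changes of dim genes toward 0. The background step, the between-array normalization, the probe annotation and the genome build are not given in the sources used here. The deposited table held 41345 probe sets for 13 arrays, with log2 values from 0.376 to 13.8. No scanner-level files were used here, so detection calls per probe set could not be made, and the number of arrays limits the precision.

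Probe sets were named from the platform annotation. In it 23521 probe sets had 1 gene symbol, 1814 had several and 16010 had none, and the last 2 kinds were left out of the gene tests. The Entrez identifiers of 23328 probe sets with 1 symbol matched a RefSeq table of the mouse assembly GRCm38.p6, and 0 symbols changed through that match. No coordinates were taken from that table. For the 1082 genes with more than 1 probe set, the probe set with the highest mean over all arrays was used, which left 22180 genes. Probe sets of close gene family members, such as the H2 class I genes, the Gbp and Irgm GTPases and Orm1 and Orm2, can take signal from each other, so their values are uncertain as to the member.

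All 13 arrays entered 1 limma fit (lmFit and eBayes, default settings, limma 3.58.1 in R 4.3.3), with no covariates, and the comparisons LPS vs control, LPS/LPS vs control and LPS/LPS vs LPS were taken from it, with a moderated F-test over the 3 groups. Differences are log2 differences with limma's moderated standard error (SE), and p-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. Gene lists were tested two-sided with limma's camera at a preset inter-gene correlation of 0.01, adjusted over the 40 lists with at least 5 measured members. Camera with an estimated correlation per list and fry, which asks whether the genes of a list move on balance in 1 direction, stand beside it. The 41 lists fixed were markers of the proximal tubule (S1 and S2, S3), of other nephron segments, podocytes, endothelium, fibroblasts and mural cells, macrophages and monocytes, neutrophils, lymphocytes and erythrocytes. They also held genes of LPS sensing, negative regulators of its signalling, cytokines, interferon-stimulated genes, MHC class I and II presentation, complement, acute phase, tubular injury, NRF2 targets, NADPH oxidases, metal handling, and JAK-STAT3 signalling. The metabolic and housekeeping lists covered oxidative phosphorylation, the tricarboxylic acid cycle, fatty acid oxidation, gluconeogenesis, glycolysis, sterol synthesis, and NAD and arginine metabolism. The remaining lists covered the unfolded protein, integrated stress and heat shock responses, translation factors, ribosomal proteins, proteasome, autophagy, cell cycle, cell death, tight junctions and the clock. Counts of list members past the threshold are given over all genes and adjusted over the list alone.

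The design, the gene lists, the settings varied and the rule for named genes were fixed before the data were examined. The rule takes, per comparison, the 6 largest rises and the 6 largest falls among genes past the threshold whose groups do not overlap. It leaves out predicted genes, small RNAs, receptor families with many copies and probe sets with several or no symbols. It adds up to 4 called members of each described list, or else the member with the lowest p, and Tlr4, Cd14, Lcn2, Havcr1, Slc5a2 and Slc34a1 in every comparison. Lists are described where they pass camera, where at least 3 members are called, or where they mark another cell type. Other genes named in the text were chosen after their values were seen.

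Without detection calls, the 95th percentile of the mean levels of 1105 olfactory receptor genes, a family taken here as mostly silent in this tissue, served as a background reference. It lay at a log2 level of 4.77, and 2207 of the genes tested had a mean above it. This reference was chosen after seeing the data. So was a split of the arrays by the standard deviation (SD) of their log2 values at 1.328 into 7 wide and 6 narrow arrays, used for within-class values and as a block.

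The fits were tested on simulated data for 22180 genes with limma's moderated spread of each gene. Noise was drawn independently for each gene, and 50 genes were changed at each size. In the simulated LPS vs control comparison, 60% of genes changed by a log2 difference of 1 were recovered and 100% of those changed by 2. In the simulated LPS/LPS vs control comparison these shares were 72% and 94%, and in LPS/LPS vs LPS 68% and 98%. Of genes changed by 0.5, 6%, 8% and 2% were recovered in that order of comparisons, and 9, 11 and 9 unchanged genes were called. The adjusted threshold depends on how many genes change, so these shares do not carry over to the real data. There 0 genes were called in LPS vs control, although the gene H2-T23 differed by 2.30. Shared controls were treated by simulating unchanged groups against the same arrays and by splitting the 4 controls. Alternatives covered a filter on dim genes, scaling by array medians, quantile normalization, eBayes with trend and robust settings, array weights, a replicate block, smaller fits, other probe set choices, a fold threshold, fits without moderation, and leaving out each replicate. The spread class as a block, the joint omission of LPS replicate 4 and LPS/LPS replicate 5, and calls at an unadjusted p were added after seeing the data. Plots were drawn with matplotlib 3.10.9 in Python 3.11.15.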

Results

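The S1 segment is the first stretch of the proximal tubule, where filtered glucose, amino acids, phosphate and proteins are reclaimed. Gene expression was profiled in S1 segments of male C57BL/6J mice with Affymetrix whole-transcript arrays, with 1 array per sample and 13 arrays in all. The control group, with 4 arrays, received saline. The LPS group, with 4 arrays, received 5 mg/kg of LPS, the endotoxin of Gram-negative bacteria, into the peritoneum and was studied at 24 h. The LPS/LPS group, with 5 arrays, received 0.25 mg/kg, then 5 mg/kg after 24 h, a schedule called endotoxin preconditioning. The labels do not state that each array came from a separate animal, so p-values measure only the spread between these samples.

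Array medians of the RMA log2 values ranged from 3.56 to 3.68, and correlations across genes between pairs of arrays ranged from 0.744 to 0.897. The highest joined 2 arrays of different groups, LPS replicate 4 and LPS/LPS replicate 5. The mean correlation was 0.837 within groups and 0.8345 between groups, so arrays of a group were hardly more alike than arrays of different groups. Arrays did resemble others of similar spread. The mean correlation was 0.857 within the wide and narrow classes and 0.817 between them. The wide class held control replicates 1 and 4, LPS replicates 2, 3 and 4, and LPS/LPS replicates 1 and 5. The narrow class therefore held only 1 LPS array against 2 control and 3 LPS/LPS arrays, and within-class values rest on these few arrays.

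The comparison of LPS with control asked what a single large endotoxin dose does to the S1 segment. Genes of interferon signalling, MHC class I antigen presentation, the acute phase and the unfolded protein response were higher as groups by camera in the LPS samples, although no single gene passed the threshold over all genes. For MHC class I and the acute phase, median differences of 0.16 and 0.24 lay well below the means of 0.47 and 0.64. H2-T23, a non-classical MHC class I gene, had a log2 level of 3.42 ± 0.37 (SD, n = 4) in control and 5.72 ± 0.81 (SD, n = 4) in LPS, a difference of 2.30 (SE 0.35, limma adjusted p = 0.0536). Lcn2, which encodes the iron-scavenging injury marker lipocalin 2, differed by 1.81 (SE 0.30, adjusted p = 0.0638), from 3.81 ± 0.20 to 5.62 ± 0.71 (SD, n = 4 each). Cd14, the LPS co-receptor, differed by 1.497 (SE 0.28, adjusted p = 0.11), and its receptor partner Tlr4 by 0.10 (SE 0.26, adjusted p = 0.958). Slc34a1, the sodium-phosphate cotransporter of the brush border, differed by -1.19 (SE 0.37, adjusted p = 0.551), from 11.23 ± 0.23 to 10.04 ± 0.64 (SD, n = 4 each). The arrays of the 2 groups did not overlap for H2-T23, Lcn2, Cd14 or Slc34a1.

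limma called 0 genes in LPS vs control, with 1427 genes (6.43%) at an unadjusted p under 0.05, of which 773 were higher and 654 lower. The lowest adjusted p of 0.0536 was shared by 7 genes, chosen after their values were seen: H2-T23, the interferon-inducible GTPases Iigp1 (1.69) and Gbp10 (2.22), the lipid droplet coat gene Plin2 (1.91), Plac8 (1.53), Snord19 (1.76) and Olfr218 (-1.43). Of these only Iigp1 and Gbp10 had a mean over all arrays above the background reference, and Olfr218 belongs to the family that set it. Lcn2 and Cd14 also had means over all arrays below it. The LPS means of H2-T23 (5.72), Lcn2 (5.62), Plin2 (5.42), Plac8 (5.29) and Cd14 (5.22) lay above it, and those of Snord19 (3.45) and Olfr218 (2.71) did not. Where a group level lies below the reference, the size of a change is uncertain. At an adjusted p under 0.1 there were 18 genes, 15 of them higher. The groups did not overlap for 698 genes, or 3.15%, where chance gives 2.86%. With array weights, limma called 30 genes, and without LPS replicate 1 it called 24. Other settings called between 0 and 9 genes, and the per-gene linear model without moderation called 0.

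Of the 40 lists, 16 rose in LPS vs control and 0 fell by camera, and 6 of the 16 also passed with an estimated correlation. Fry put 7 lists past the threshold, these 6 and LPS sensing, which camera did not pass. Without LPS replicate 3 the calls of 9 lists were lost: oxidative phosphorylation, tricarboxylic acid cycle, fatty acid oxidation, proteasome (mean 0.11), autophagy (mean 0.14), translation, complement, endothelial and JAK-STAT3 genes. The autophagy and oxidative phosphorylation calls were also lost without control replicate 2 or 3, the tricarboxylic acid cycle call without control replicate 2, and the complement call without control replicate 2 or 4 or LPS replicate 4. Over all genes, 0 members of any list passed the gene test in this comparison, so counts of members below are adjusted over the list alone.

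Interferon-stimulated genes rose with a mean log2 difference of 0.29 (adjusted p = 1.12e-06, and adjusted p = 0.0162 with an estimated correlation), and 28 of 38 measured members had positive differences. Only 2 of the 38 had a mean above the background reference, so sizes of change in this list are uncertain in every comparison. Higher adjusted over the list alone were 4 members: Iigp1 (1.69), Irgm1 (1.68) and Igtp (1.56), GTPases of defence against intracellular pathogens, and Rtp4 (0.62). The list mean was 0.26 within the wide arrays and 0.37 within the narrow ones. MHC class I and immunoproteasome genes rose by a mean of 0.47 (adjusted p = 0.00198, and adjusted p = 0.0479 with an estimated correlation), with 4 of 17 members higher adjusted over the list alone. These were B2m (2.90), the light chain of class I molecules, H2-T23 (2.30), H2-K1 (1.37) and the peptide-loading chaperone Tapbp (1.08). The class I median was 0.16, with 13 of 17 members positive, so these 4 carried much of the mean. MHC class II genes rose by 0.47 (adjusted p = 0.00424, but adjusted p = 0.0875 with an estimated correlation). Adjusted over the list alone, 1 of 8 members was higher, the class II beta chain gene H2-Ab1 (2.16). The class II mean was 0.64 within the wide arrays and 0.05 within the narrow ones, and 2 of the 8 members had a mean above the background reference. Markers of macrophages and monocytes, which carry class II molecules, had a mean difference of 0.05 over 22 genes (adjusted p = 0.541). Only 1 of the 22 had a mean above the background reference, so this flat mean says little about macrophage content.

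Acute phase and coagulation genes rose by a mean of 0.64 (adjusted p = 4.54e-06, and adjusted p = 0.0479 with an estimated correlation). The median difference was 0.24, with 13 of 23 members positive and 10 negative. Adjusted over the list alone, 7 of 23 members were higher, and they carried much of the mean. The fibrinogen chain genes Fgg (2.95), Fgb (2.19) and Fga (1.71), the orosomucoids Orm2 (2.57) and Orm1 (0.81), Lcn2 (1.81) and the serum amyloid gene Saa2 (1.59) made up the 7. The list mean was 0.74 within the wide arrays and 0.35 within the narrow ones. Complement genes rose by 0.20 (adjusted p = 0.0212, but adjusted p = 0.124 with an estimated correlation), with 0 of 14 members past the threshold adjusted over the list alone. Its lowest p belonged to Cfb, complement factor B (0.84), and the list mean was 0.30 within the wide and -0.03 within the narrow arrays. Tubular injury markers rose by 0.21 (adjusted p = 0.00404, but adjusted p = 0.269 with an estimated correlation). Adjusted over the list alone, 3 of 27 were higher: Lcn2, the cytokeratin gene Krt20 (1.05), and Havcr1 (0.76, SE 0.20), which encodes kidney injury molecule. JAK-STAT3 and growth factor genes rose by 0.21 (adjusted p = 0.0078, and adjusted p = 0.0479 with an estimated correlation). Adjusted over the list alone, 2 of 23 were higher, the transcription factor genes Klf6 (1.48) and Stat3 (0.87).

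Unfolded protein response genes, which restore folding capacity in the endoplasmic reticulum, rose by 0.37 (adjusted p = 4.57e-06, and adjusted p = 0.0298 with an estimated correlation). Of 22 members 18 had positive differences, 0 passed adjusted over the list alone, and the chaperone gene Hspa5 had the lowest p (0.71). The list mean was 0.40 within the wide and 0.15 within the narrow arrays. Metallothionein, iron and zinc genes rose by 0.35 (adjusted p = 0.000159, and adjusted p = 0.023 with an estimated correlation). In this list 1 of 12 was higher adjusted over the list alone, the metallothionein gene Mt1 (1.21).

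Proteasome genes rose by 0.23 (adjusted p = 0.000283, but adjusted p = 0.0986 with an estimated correlation), with 0 of 27 past the threshold adjusted over the list alone and Psmd11 (0.54) leading. Translation factors and ribosome biogenesis genes rose by 0.23 (adjusted p = 0.00818, but adjusted p = 0.0875 with an estimated correlation). Eif6 (1.18) and the cap-binding factor gene Eif4e (0.75) were higher adjusted over the list alone, 2 of 25 members. Autophagy, lysosome and mitophagy genes rose by 0.29 (adjusted p = 0.0117, but adjusted p = 0.295 with an estimated correlation), with 0 of 22 past the threshold adjusted over the list alone and the cathepsin gene Ctsl (1.24) leading.

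Mitochondrial lists moved with individual arrays. Fatty acid oxidation and peroxisome genes rose by 0.36 (adjusted p = 3.82e-05, but adjusted p = 0.216 with an estimated correlation). Of its 27 members, 3 were higher adjusted over the list alone: Pdk4 (2.00), the kinase that restrains pyruvate oxidation, and the acyl-CoA dehydrogenase genes Acadvl (0.98) and Acadl (0.91). The list mean was 0.47 within the wide arrays and -0.09 within the narrow ones, and without LPS replicate 3 it was 0.14 and no longer passed (adjusted p = 0.0895). Oxidative phosphorylation genes rose by 0.23 (adjusted p = 0.00852, but adjusted p = 0.637 with an estimated correlation), with 0 of 39 past the threshold adjusted over the list alone and the complex I gene Ndufa10 (0.58) leading. Without LPS replicate 3 the mean was -0.17. Tricarboxylic acid cycle genes rose by 0.21 (adjusted p = 0.00818, but adjusted p = 0.489 with an estimated correlation), with 0 of 21 past the threshold adjusted over the list alone and the fumarase gene Fh1 (0.67) leading. Without LPS replicate 3 the mean was -0.03. Within the narrow arrays the mean was -0.06 for oxidative phosphorylation and -0.14 for the cycle.

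Among markers of other cells, endothelial markers rose by 0.19 in LPS vs control (adjusted p = 0.00424, but adjusted p = 0.0875 with an estimated correlation), with 0 of 15 past the threshold adjusted over the list alone and Pecam1 (0.75) leading. Neutrophil markers (mean -0.17, adjusted p = 0.0819, Elane -0.36), lymphocyte markers (-0.14, adjusted p = 0.191, Klrb1c -0.86) and fibroblast and mural cell markers (0.14, adjusted p = 0.108, Tagln 0.54) did not pass. Nor did markers of the loop, distal tubule and collecting duct (0.13, adjusted p = 0.433, Slc12a3 0.94), the S3 segment (0.07, adjusted p = 0.409, Cyp7b1 0.28) or podocytes (-0.01, adjusted p = 0.766). Of 9 podocyte markers 1 was higher adjusted over the list alone, the slit diaphragm adaptor gene Cd2ap (0.73). The 3 erythrocyte markers measured, too few for a list test, had a mean difference of 0.03, with Slc4a1 at 0.09, and Ly6c2 led the macrophage markers (0.43). Only 0 of 14 neutrophil, 1 of 13 lymphocyte and 1 of 22 macrophage markers had means above the background reference. Flat means of these lists, here and below, therefore say little about such cells. S1 and S2 markers did not pass (mean 0.03, adjusted p = 0.719), and Slc5a2, the glucose transporter of this segment, differed by -0.28 (SE 0.16, adjusted p = 0.789). Genes of LPS sensing (0.14, adjusted p = 0.12 by camera, though 0.035 by fry), negative regulators of that signalling (0.08, adjusted p = 0.12) and cytokines and chemokines (0.03, adjusted p = 0.696) did not pass either. In that order, 0 of 18, 1 of 22 and 2 of 32 members had means above the background reference.

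**Figure D1:**
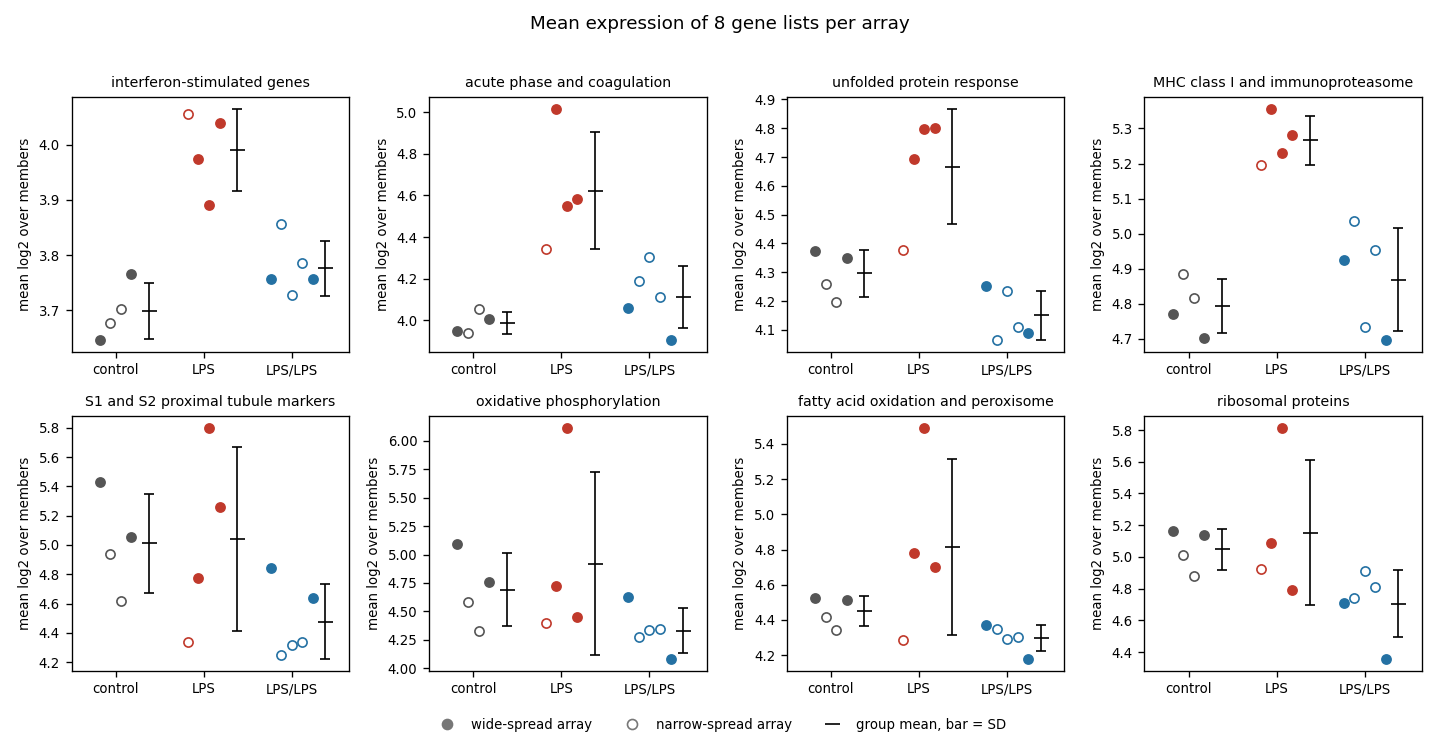
Mean log2 expression over the members of 8 gene lists (vertical axes) on each of the 13 arrays by group (horizontal axis); filled points are wide-spread arrays, open points narrow-spread arrays, and bars give the group mean ± SD. For interferon-stimulated genes the LPS arrays lie between 3.89 and 4.06 and the control arrays between 3.65 and 3.77, while LPS replicate 3 stands alone in oxidative phosphorylation at 6.12.

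The comparison of LPS/LPS with control asked how preconditioned and challenged S1 segments differ from untreated ones. Genes of the mature proximal tubule and of its metabolism were lower as groups by camera at its preset correlation, but 0 of the 40 lists passed with an estimated correlation or with fry. The interferon, acute phase and antigen presentation lists did not pass in any of these tests. Cndp2, a cytosolic dipeptidase gene, fell by 2.02 (SE 0.24, limma adjusted p = 0.0164), from a log2 level of 6.76 ± 0.44 (SD, n = 4) to 4.74 ± 0.47 (SD, n = 5), with no overlap of arrays. It differed by -1.94 within the wide arrays and -2.00 within the narrow ones. The predicted gene Gm12770, outside the rule and chosen after its values were seen, rose by 1.00 (SE 0.14, adjusted p = 0.0477), with both group means below the background reference. Slc34a1 differed by -2.01 (SE 0.35, adjusted p = 0.197), with values of -1.24 within the wide and -2.53 within the narrow arrays.

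These were the 2 genes that limma called in LPS/LPS vs control, with 1042 genes (4.70%) at an unadjusted p under 0.05. The groups did not overlap for 341 genes, or 1.54%, where chance gives 1.59%. Both calls were lost without control replicate 1, without control replicate 4, or without LPS/LPS replicate 3. They were also lost, with 0 genes called, in a fit of only the 2 groups compared, with replicate numbers as a block, over all probe sets of the table, and without moderation.

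By camera, 9 lists fell and 1 rose in LPS/LPS vs control. Without control replicate 1 only 3 lists passed, those of S1 and S2 markers, oxidative phosphorylation (mean -0.23) and ribosomal proteins, and the gluconeogenesis mean was -0.20. The translation, autophagy, proteasome and fibroblast calls were also lost on leaving out other single arrays. Over all genes, 0 members of any list passed.

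S1 and S2 proximal tubule markers fell by a mean of 0.53 (adjusted p = 2.02e-09, but adjusted p = 0.449 with an estimated correlation), and 28 of 30 members had negative differences. Adjusted over the list alone, 2 members were lower, Slc34a1 and the organic cation transporter gene Slc22a2 (-1.86). The mean was -0.50 within the wide arrays and -0.48 within the narrow ones. Gluconeogenesis and amino acid catabolism genes fell by 0.32 (adjusted p = 0.000229, but adjusted p = 0.449 with an estimated correlation). G6pc (-1.15), which releases free glucose, and the inositol oxygenase gene Miox (-1.32) were lower adjusted over the list alone, 2 of 27 members. NRF2 targets and antioxidant enzymes fell by 0.27 (adjusted p = 0.00107, but adjusted p = 0.272 with an estimated correlation), with 0 of 28 past the threshold adjusted over the list alone and the secreted glutathione peroxidase gene Gpx3 (-1.05) leading.

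Oxidative phosphorylation genes fell by 0.36 (adjusted p = 5.87e-06, but adjusted p = 0.532 with an estimated correlation), with 35 of 39 negative, 0 past the threshold adjusted over the list alone, and the ATP synthase gene Atp5b (-1.21) leading. The mean was -0.57 within the wide arrays and -0.14 within the narrow ones. Tricarboxylic acid cycle genes fell by 0.24 (adjusted p = 0.00137, but adjusted p = 0.532 with an estimated correlation), with 0 of 21 past the threshold adjusted over the list alone and Mdh2 (-0.52) leading. Ribosomal protein genes fell by 0.34 (adjusted p = 3.57e-05, but adjusted p = 0.449 with an estimated correlation), with 29 of 34 negative, 0 past the threshold adjusted over the list alone, and Rpl38 (-1.52) leading. The ribosomal mean was -0.62 within the wide arrays and -0.13 within the narrow ones. Translation factors fell by 0.21 (adjusted p = 0.0369, but adjusted p = 0.449 with an estimated correlation), with 0 of 25 past the threshold adjusted over the list alone. The elongation factor gene Eef1a1 led them (-2.13), and its dimmer probe set gave -0.27. Proteasome genes fell by 0.13 (adjusted p = 0.0165, but adjusted p = 0.449 with an estimated correlation), with 0 of 27 past the threshold adjusted over the list alone. The proteasome gene with the lowest p, Psmd3, was higher (0.36). Autophagy, lysosome and mitophagy genes fell by 0.22 (adjusted p = 0.0234, but adjusted p = 0.449 with an estimated correlation). Here 1 of 22 was lower adjusted over the list alone, the autophagosome gene Gabarapl1 (-1.65), and the list mean was -0.45 within the wide and -0.02 within the narrow arrays.

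Fibroblast and mural cell markers rose by 0.14 in LPS/LPS vs control (adjusted p = 0.0369, but adjusted p = 0.449 with an estimated correlation). In this list 1 of 14 was higher adjusted over the list alone, the collagen gene Col1a2 (0.48), whose dimmer probe set gave 0.11. Endothelial markers (0.14, adjusted p = 0.061, Egfl7 0.30), macrophage and monocyte markers (0.10, adjusted p = 0.327, Mrc1 0.53), neutrophil markers (-0.01, adjusted p = 0.86, Ltf 0.20) and lymphocyte markers (-0.03, adjusted p = 0.745, Cd3e 0.29) did not pass. The same held for S3 markers (-0.25, adjusted p = 0.215), other nephron segments (0.02, adjusted p = 0.86, Aqp4 0.35) and podocyte markers (0.00, adjusted p = 0.86, Podxl -0.24). Of 13 S3 markers 1 was lower adjusted over the list alone, Atp11a (-1.42), though its dimmer probe set gave -0.19. The 3 erythrocyte markers had a mean difference of 0.10, with Epb42 at 0.16. Interferon-stimulated genes (0.08, adjusted p = 0.407), acute phase genes (0.13, adjusted p = 0.357) and MHC class I genes (0.08, adjusted p = 0.86) did not pass. Lcn2 differed by 0.76 (SE 0.29), Tlr4 by 0.33 (SE 0.25), Havcr1 by 0.14 (SE 0.19), Cd14 by 0.13 (SE 0.26) and Slc5a2 by -0.37 (SE 0.15), none past the threshold.

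The comparison of LPS/LPS with LPS asked whether the small dose given 24 h earlier alters the state of the S1 segment after the same challenge. All 14 genes called were lower in the preconditioned samples, and 9 of them had a mean over all arrays below the background reference of 4.77, where the size of a change is uncertain: H2-T23, Timp3, Irgm1, Ezr, Lap3, Gbp11, Psmd11, Snord19 and Mir196a-1. Of these 9, H2-T23, Timp3, Ezr, Psmd11 and Mir196a-1 had LPS means above the reference, and Irgm1, Lap3, Gbp11 and Snord19 did not. Guca2b, which encodes the natriuretic peptide uroguanylin, fell by 3.11 (SE 0.40, limma adjusted p = 0.0111), from 9.34 ± 0.68 (SD, n = 4) to 6.22 ± 0.73 (SD, n = 5). H2-T23 fell by 3.01 (SE 0.33, adjusted p = 0.006), to a log2 level of 2.71 ± 0.43 (SD, n = 5), which lies in the background range, so only its LPS level stands above the reference. Malat1, an abundant nuclear long non-coding RNA, fell by 2.26 (SE 0.29, adjusted p = 0.0111), from 9.61 ± 0.48 (SD, n = 4) to 7.34 ± 0.59 (SD, n = 5). Its other probe set was dim, with a mean of 2.496, and differed by -0.24. The LPS means of all 14 genes also lay above control, on the same 4 LPS arrays, so the falls are not independent of those rises. In LPS/LPS vs control, Guca2b differed by -1.34, Malat1 by -1.50, Timp3 by -1.21 and Irgm1 by 0.005, and none of the 14 passed the threshold.

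Fam133b fell by 1.92 (SE 0.30, adjusted p = 0.0337), and Timp3, an inhibitor of matrix metalloproteinases, fell by 1.71 (SE 0.20, adjusted p = 0.00683). The interferon-inducible GTPase gene Irgm1 fell by 1.68 (SE 0.27, adjusted p = 0.0417). These 6 genes had no overlap between the 9 arrays, and within the narrow class, with 1 LPS array, they differed by -1.27 to -2.32. The remaining 8, most of them outside the rule and chosen after their values were seen, were the membrane-cytoskeleton linker gene Ezr (-1.57), the thioredoxin inhibitor gene Txnip (-1.56), the leucine aminopeptidase gene Lap3 (-1.41), Naca (-1.37), Gbp11 (-1.08), Psmd11 (-0.90), Snord19 (-1.71) and Mir196a-1 (-1.58). At an unadjusted p under 0.05 there were 1910 genes (8.61%), and all 37 genes at an adjusted p under 0.1 were lower. The groups did not overlap for 533 genes, or 2.40%, where chance gives 1.59%. The number of genes called was 96 without LPS replicate 1, 5 without LPS/LPS replicate 2, 3 or 5, and 1 with LPS replicate 4 and LPS/LPS replicate 5 both left out. It was 0 without moderation, 2 in a fit of only the 2 groups compared, 4 with replicate numbers as a block, and 7 over all probe sets of the table.

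**Figure D2:**
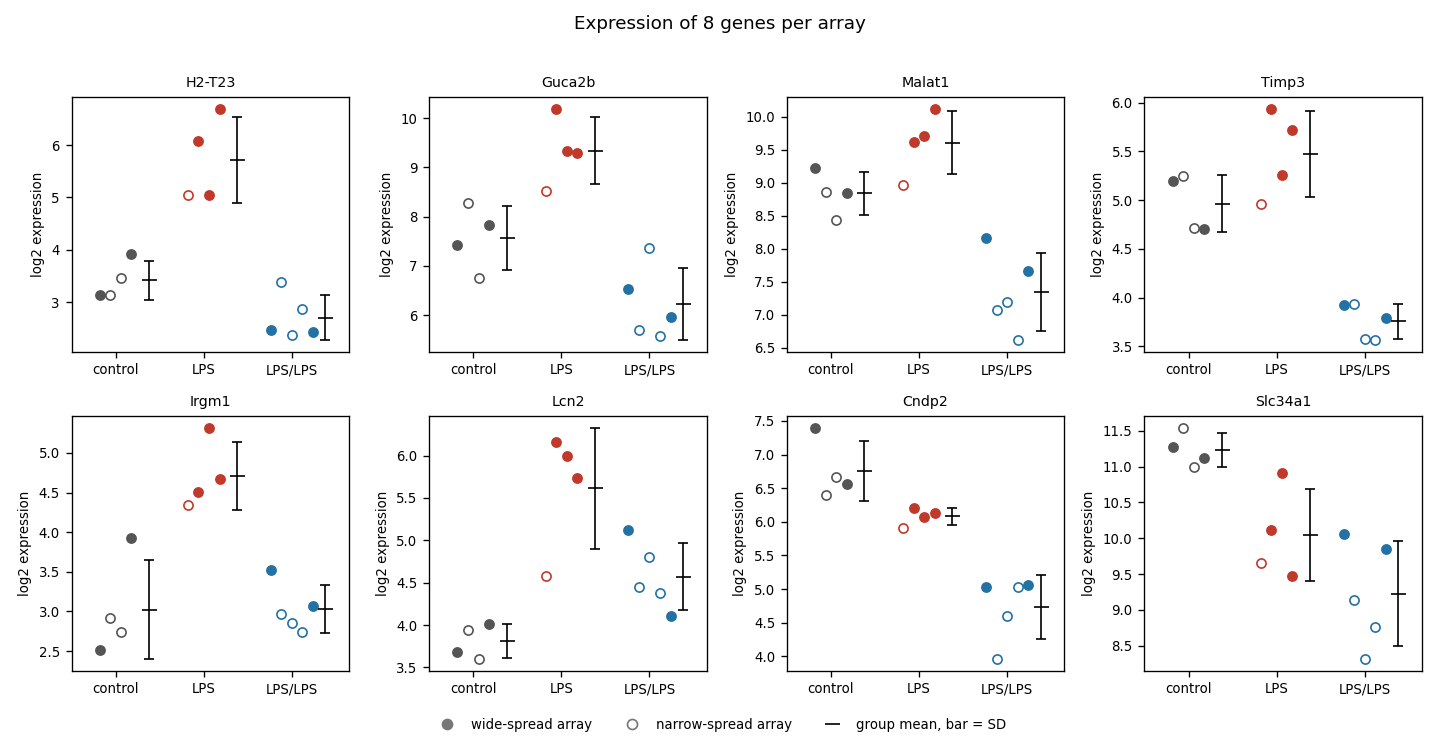
Log2 expression (vertical axes) of 8 genes on each of the 13 arrays by group (horizontal axis); filled points are wide-spread arrays, open points narrow-spread arrays, and bars give the group mean ± SD. H2-T23, Guca2b, Malat1, Timp3 and Irgm1 were called in LPS/LPS vs LPS and their LPS/LPS arrays lie below all LPS arrays, and Cndp2 has a mean of 6.76 in control, 6.08 in LPS and 4.74 in LPS/LPS.

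By camera, 20 lists fell in LPS/LPS vs LPS and 0 rose, and 8 of the 20 also passed with an estimated correlation. Fry put 11 lists past the threshold. Leaving out single arrays ended 3 calls: tubular injury markers without LPS replicate 2 or LPS/LPS replicate 5 (mean -0.06 without the latter), negative regulators without LPS replicate 2 or LPS/LPS replicate 4, and S3 markers without LPS replicate 3 (mean -0.17) or LPS/LPS replicate 3, 4 or 5. Over all genes 3 list members were lower, namely H2-T23, Irgm1 and Psmd11.

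The interferon, MHC and acute phase lists, which rose in LPS vs control, fell here. Both comparisons use the same 4 LPS arrays, so for any list the fall is not independent of the rise. How much of it the shared arrays alone would give was not estimated for lists. Interferon-stimulated genes fell by a mean of 0.21 (adjusted p = 2.11e-05, and adjusted p = 0.0179 with an estimated correlation). Of 38 members 1 was lower over all genes and 3 were lower adjusted over the list alone: Irgm1 (-1.68), Igtp (-1.52) and Iigp1 (-1.43). The mean was -0.21 within the wide and -0.27 within the narrow arrays. MHC class I and immunoproteasome genes fell by 0.40 (adjusted p = 0.00241, and adjusted p = 0.0456 with an estimated correlation), with 1 of 17 lower over all genes and 2 adjusted over the list alone, H2-T23 and Tapbp (-0.73). The class I median was -0.095, with 11 of 17 members negative, and quantile normalization ended this call (mean -0.30). MHC class II genes fell by 0.47 (adjusted p = 0.00241, but adjusted p = 0.0611 with an estimated correlation). H2-Ab1 (-1.88) was the 1 of 8 lower adjusted over the list alone, and the class II mean was -0.65 within the wide and -0.05 within the narrow arrays. Acute phase and coagulation genes fell by 0.51 (adjusted p = 4.58e-05, but adjusted p = 0.0611 with an estimated correlation). Of its 23 members, 6 were lower adjusted over the list alone, among them Orm2 (-2.46), Fgg (-2.40) and Fgb (-1.98), and Il1rn, which encodes the interleukin-1 receptor antagonist, was higher (0.53). The acute phase median was -0.20, with 15 of 23 members negative. The acute phase mean was -0.73 within the wide and -0.14 within the narrow arrays.

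JAK-STAT3 and growth factor genes fell by 0.18 (adjusted p = 0.00648, and adjusted p = 0.0453 with an estimated correlation), with 0 of 23 past the threshold adjusted over the list alone and Klf6 (-0.88) leading. This call was lost when only genes with a mean above the median were tested. Negative regulators of Toll-like receptor and NF-kB signalling fell by 0.10 (adjusted p = 0.0265, but adjusted p = 0.115 with an estimated correlation), with 0 of 22 past the threshold adjusted over the list alone and the NF-kB inhibitor gene Nfkbia (-0.66) leading. Only 1 of the 22 had a mean above the background reference. Tubular injury markers fell by 0.13 (adjusted p = 0.0195, but adjusted p = 0.328 with an estimated correlation), with 0 of 27 past the threshold adjusted over the list alone. Lcn2 differed by -1.04 (SE 0.29), with -1.35 within the wide and -0.04 within the narrow arrays, and Havcr1 by -0.62 (SE 0.19). Cd14 differed by -1.37 (SE 0.26, adjusted p = 0.0919) and Tlr4 by 0.23 (SE 0.25). Complement genes did not pass (-0.16, adjusted p = 0.0772), although Cfb (-1.34) was 1 of 14 lower adjusted over the list alone.

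Unfolded protein response genes fell by 0.52 (adjusted p = 3.16e-10, and adjusted p = 0.0131 with an estimated correlation). Here 10 of 22 were lower adjusted over the list alone, among them Hsp90b1 (-1.37), an endoplasmic reticulum chaperone gene, the transcription factor gene Xbp1 (-1.09), Herpud1 (-0.88) and Hspa5 (-0.85). The list mean was -0.59 within the wide and -0.24 within the narrow arrays. Translation factors fell by 0.44 (adjusted p = 1.78e-06, and adjusted p = 0.0136 with an estimated correlation), with 8 of 25 lower adjusted over the list alone, led by the elongation factor genes Eef1a1 (-2.74) and Eef2 (-2.22). The dimmer Eef1a1 probe set gave -0.68. Proteasome genes fell by 0.36 (adjusted p = 2.78e-09, and adjusted p = 0.0179 with an estimated correlation). Among them 1 of 27 was lower over all genes, Psmd11, and 3 adjusted over the list alone, with Psmb5 (-1.16) and Psmc2 (-0.70). NRF2 targets and antioxidant enzymes fell by 0.38 (adjusted p = 1.16e-05, and adjusted p = 0.0179 with an estimated correlation), with 8 of 28 lower adjusted over the list alone, among them the ferritin gene Fth1 (-1.84), Gpx1 (-1.77), Gpx3 (-1.49) and the glutathione reductase gene Gsr (-1.10). Metallothionein, iron and zinc genes fell by 0.35 (adjusted p = 0.00106, and adjusted p = 0.0252 with an estimated correlation). Of these, 2 of 12 were lower adjusted over the list alone, Fth1 and Mt1 (-1.26).

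Tubule and energy metabolism lists also fell, but each call was lost with an estimated correlation, and the differences were small within the narrow arrays. Without LPS replicate 3 the means shrank to -0.31 for S1 and S2 markers, -0.19 for gluconeogenesis, -0.22 for the tricarboxylic acid cycle and -0.23 for ribosomal proteins. S1 and S2 markers fell by 0.57 (adjusted p = 3.63e-09, but adjusted p = 0.155 with an estimated correlation), with a mean of -0.54 within the wide and -0.04 within the narrow arrays. In this list 3 of 30 were lower adjusted over the list alone: the bicarbonate cotransporter gene Slc4a4 (-1.33) and the amino acid transporter genes Slc6a18 (-1.20) and Slc6a19 (-0.91). Slc34a1 differed by -0.81 (SE 0.35) and Slc5a2 by -0.09 (SE 0.15). S3 markers fell by 0.32 (adjusted p = 0.031, but adjusted p = 0.303 with an estimated correlation), with 1 of 13 lower adjusted over the list alone, Atp11a (-1.82), whose dimmer probe set gave -0.04. Gluconeogenesis and amino acid catabolism genes fell by 0.41 (adjusted p = 1.77e-06, but adjusted p = 0.141 with an estimated correlation), with 0 of 27 past the threshold adjusted over the list alone and the tyrosine catabolism gene Fah (-1.14) leading. The gluconeogenesis mean was -0.52 within the wide and 0.02 within the narrow arrays.

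Oxidative phosphorylation genes fell by 0.59 (adjusted p = 2.78e-11, but adjusted p = 0.166 with an estimated correlation), with 36 of 39 negative, 0 past the threshold adjusted over the list alone, and Ndufa2 (-1.74) leading. The mean was -0.74 within the wide and -0.09 within the narrow arrays, and -0.19 without LPS replicate 3. Fatty acid oxidation genes fell by 0.52 (adjusted p = 3.16e-10, but adjusted p = 0.0592 with an estimated correlation). Of its 27 members, 4 were lower adjusted over the list alone: Pdk4 (-1.66), Ehhadh (-1.60), the carnitine transferase gene Cpt1a (-1.18) and Acadl (-1.06). That mean was -0.72 within the wide and 0.03 within the narrow arrays, and -0.29 without LPS replicate 3. Tricarboxylic acid cycle genes fell by 0.45 (adjusted p = 1.37e-08, but adjusted p = 0.115 with an estimated correlation), with 2 of 21 lower adjusted over the list alone, Dlst (-0.80) and Fh1 (-0.74). Ribosomal protein genes fell by 0.45 (adjusted p = 1.18e-06, but adjusted p = 0.115 with an estimated correlation). Here 4 of 34 were lower adjusted over the list alone, among them Rpl38 (-1.82) and Rpl22 (-0.70), and 2 were higher, Rplp0 (0.62) and Rps23 (0.62). Autophagy, lysosome and mitophagy genes fell by 0.50 (adjusted p = 2.05e-06, but adjusted p = 0.0611 with an estimated correlation). In this list 7 of 22 were lower adjusted over the list alone, among them Gabarapl1 (-1.78) and the lysosomal genes Ctsl (-1.54), Lamp2 (-1.30) and Lamp1 (-1.20).

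Markers of other cells did not pass in LPS/LPS vs LPS. The mean was 0.16 for neutrophil markers (adjusted p = 0.119, Elane 0.42), 0.12 for lymphocyte markers (adjusted p = 0.413, Cd3e 0.32) and 0.05 for macrophage and monocyte markers (adjusted p = 0.72, Laptm5 0.48). It was -0.06 for endothelial markers (adjusted p = 0.293, Pecam1 -0.57), 0.00 for fibroblast and mural cell markers (adjusted p = 0.74, Lum 0.37) and -0.11 for other nephron segments (adjusted p = 0.565, Cldn16 0.37). Podocyte markers had a mean of 0.01 (adjusted p = 0.618), with Cd2ap (-0.60) and Tcf21 (-0.35) lower and Wt1 (0.52) higher adjusted over the list alone, and the 3 erythrocyte markers a mean of 0.07, with Epb42 at 0.20.

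**Figure D3:**
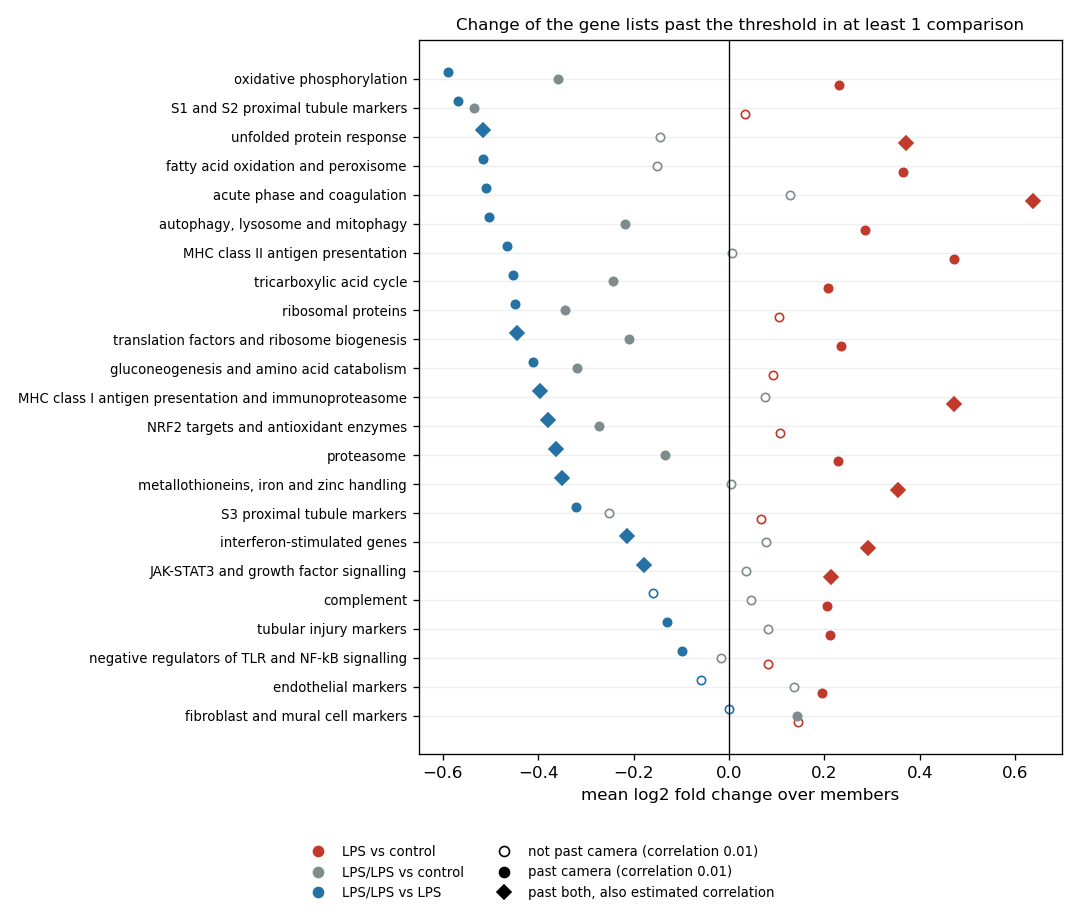
Mean log2 difference over list members (horizontal axis) for the lists past camera's threshold in at least 1 comparison (vertical axis), by comparison; open symbols did not pass, filled circles passed at the preset correlation of 0.01, and diamonds passed with an estimated correlation too. Interferon-stimulated genes stand at 0.29 in LPS vs control and -0.21 in LPS/LPS vs LPS, and oxidative phosphorylation at 0.23 and -0.59. Both comparisons use the same 4 LPS arrays, so their values are not independent.

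For every list past the threshold, mean, median and test had the same sign. The F-test over the 3 groups called 14 genes, with 1533 at an unadjusted p under 0.05. They were H2-T23, Guca2b, Malat1, Timp3, Txnip, Gbp11, Snord19 and Mir196a-1, which were also called in LPS/LPS vs LPS, Cndp2 and Gm12770, and, chosen after their values were seen, Gbp10, Iigp1, Plin2 and BC024386.

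Against control, 0 genes were called in both LPS groups, an outcome fixed by the 0 genes called in LPS vs control. At an unadjusted p under 0.05, 213 genes changed the same way in both. Unchanged groups simulated against the same controls gave a mean of 258.4, and independent lists would share 33.84. When the 4 controls were split so that each comparison had its own 2, between 37 and 45 genes changed the same way and between 13 and 80 in opposite directions. These separate fits hold fewer arrays, so their counts cannot be set beside the 213. The correlation of the differences across genes was 0.3745, against 0.528 simulated, and the covariance was 0.0269 against 0.0300, a difference of -0.00311. With split controls the correlation ranged from -0.162 to 0.0984. The count of genes called in LPS vs control and, back toward the control level, in LPS/LPS vs LPS was 0 (limma). It too had to be 0, because no gene was called in LPS vs control, so it tests nothing. At an unadjusted p under 0.05, 600 of the 1427 genes that differed in LPS moved back toward control in LPS/LPS, 431 of them genes higher in LPS and 169 lower. Simulated groups with 1 common mean for both LPS groups gave 330.4 such genes, among a mean of 2986 that differed from control there. With bases this unlike, neither the counts nor the shares can be set side by side. With all groups unchanged the simulation gave 258.2. The opposite movement, further from control, was seen for 5 genes, where the simulation with 1 common mean gave 15.19. Noise in the simulations was drawn independently for each gene, while real arrays with group names dealt anew gave up to 1597 genes toward control. The simulated counts of movement toward or away from control therefore set no level of chance.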

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

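The spread class and leucocyte tests in this part were chosen only after the results were seen. Each other test was set before it was run, but the list patterns and unadjusted calls addressed came from results already seen. Within each group, the most distant array of a named gene or described list was marked where its gap to the nearest array took up an unusually large share of the group's range. That held in 13 of 258 groups, where 1 in 20, or 12.9, is the number that chance alone gives. In control these were Cd2ap (2.37, replicate 2), Havcr1 (2.85, replicate 2), Ndufa10 (5.501, replicate 1) and Pecam1 (3.11, replicate 1). In LPS they were Herpud1 (6.52, replicate 4), Mdh2 (6.29, replicate 3) and Tagln (5.17, replicate 3). In LPS/LPS they were Cyp7b1 (3.005, replicate 2), Iigp1 (4.42, replicate 2), Ltf (4.38, replicate 3) and Pecam1 (3.73, replicate 1). The means of the translation factor list (4.30, LPS/LPS replicate 3) and of the NRF2 list (4.34, LPS/LPS replicate 5) completed the 13. All stayed in the fits. A probe set without a gene symbol, 17486011, lay outside the gene test. It fell by 2.01 in LPS/LPS vs LPS (adjusted p = 0.0162 over all 41345 probe sets), and its gene is not given in the sources used here.

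The fits were repeated with group names dealt anew over the same arrays, and the counts of splits here include the real one. In LPS vs control 0 genes were called, which any split matches (35 of 35, highest other 1), so that count tests nothing. As many genes as in the real split were called in 1 of 100 splits for LPS/LPS vs control (real 2, highest other 1), 3 of 100 for LPS/LPS vs LPS (14, highest other 176) and 2 of 100 for the 3 groups (14, highest other 20). Each of these shares, from the fit of all 3 groups, is under 0.05 taken alone. They were not corrected for the number of counts tested, and in the last 2 another split called more genes. These shares argue against chance without excluding it. Fits of only the 2 groups compared, which called 0 and 2 genes in the LPS/LPS comparisons, were not split, so these shares do not cover them. For gene lists it was 3 of 35 in LPS vs control (16, highest other 22), 7 of 100 in LPS/LPS vs control (10, highest other 11) and 5 of 100 in LPS/LPS vs LPS (20, highest other 21), so chance cannot be excluded for list counts. Nor can it for genes moved toward control (9 of 100, real 600, highest other 1597) or genes changed the same way in both LPS groups (47 of 100, real 213, highest other 1402). The split that called 176 genes follows the spread class, a structure of the arrays apart from their groups, and with the class as a block 20 genes were called in LPS/LPS vs LPS. Random lists matched for expression were drawn for every list past camera: 15 of 16 in LPS vs control, 9 of 10 in LPS/LPS vs control and 17 of 20 in LPS/LPS vs LPS had a median in the outer 2.5% on the side of their change. The others were MHC class I genes in LPS vs control and LPS/LPS vs LPS, fibroblast markers in LPS/LPS vs control, and S3 and injury markers in LPS/LPS vs LPS. All these lists had been chosen for passing camera in the same data. Random genes were drawn singly, without the correlation within a list. These counts therefore address brightness only and are no further evidence against chance.

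The tubule, mitochondrial and ribosomal lists that were lower in LPS/LPS than in LPS may owe part of their difference to the arrays. Without LPS replicate 3 alone, 6 of 6 lists still passed camera at the preset correlation, with oxidative phosphorylation moving from -0.59 to -0.19. Much of the size thus rests on that array. Its part in the calls cannot be excluded, because this test is lenient. With an estimated correlation over all arrays, camera adjusted p of the 6 ranged from 0.0592 to 0.166. Other splits of the LPS and LPS/LPS arrays put a median of 6 lists past camera. All 6 of 6 lay in the lowest 2.5% of random lists matched for expression, which speaks against a lower signal of bright genes in general. With the array spread class beside the group, 1 of 6 lists, fatty acid oxidation, had a 95% interval below 0, but without the class the intervals of S1 and S2 markers, oxidative phosphorylation and gluconeogenesis already included 0, so for these the interval decides nothing. Beside the class the differences shrank less than their intervals are wide: S1 and S2 markers from -0.57 to -0.37, the tricarboxylic acid cycle from -0.45 to -0.38 (interval -0.82 to 0.07), ribosomal proteins from -0.45 to -0.44 (interval -0.93 to 0.05), and all 6 lists passed camera with the class as a block. The array spread class as a part of the cause and preconditioning cannot be told apart for these lists, because list means spread too widely between arrays of a group. Equal numbers of wide and narrow arrays in new samples would separate them.

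The interferon, acute phase and unfolded protein lists that were higher in LPS than in control were put to the same tests. With the array spread class beside the group, 3 of 3 had a 95% interval above 0 (interferon 0.30, from 0.20 to 0.40), and 3 of 3 lay in the highest 2.5% of random lists of genes of the same brightness. Leucocytes in the tubule samples could carry such genes. Of the leucocyte markers only 2 had a mean above the background reference, Cx3cr1 (-0.14) and Nkg7 (-0.13), too few to tell leucocytes in the tubule samples apart from a tubular response. In situ hybridisation for Iigp1 or Hspa5 beside a leucocyte marker would decide it.

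The 14 genes lower in LPS/LPS than in LPS were weighed against the array spread class as well. With the class as a block, 14 of 14 kept the call, so the class does not account for them.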

How the results depend on the processing

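Each setting was changed alone, and the cause of a moved count was not tested. The spread class block, the joint omission and unadjusted calls were chosen only after the results were seen. Genes called in LPS vs control (0 at first), LPS/LPS vs control (2), LPS/LPS vs LPS (14) and the 3 groups (14) moved as follows. Only genes with a mean above the median gave 9, 1, 18 and 19, with 4 moved toward control. Array medians subtracted left 1 in LPS/LPS vs control. Quantile normalization on top gave 5, 4, 9 and 7, with 1 called in both LPS groups and 3 toward control. eBayes with trend and robust gave 7 in LPS vs control and 3 toward control. Array weights gave 30, 3, 41 and 41, with 1 in both LPS groups and 14 toward control. Fits of only the 2 groups compared gave 0 in LPS/LPS vs control and 2 in LPS/LPS vs LPS. All probe sets with 1 symbol gave 1 in LPS/LPS vs control and 22 among the 3 groups. All probe sets of the table gave 0, 7 and 0 for LPS/LPS vs control, LPS/LPS vs LPS and the 3 groups. The per-gene linear model without moderation gave 0 and 0 in the LPS/LPS comparisons. The array spread class as a block gave 4 in LPS/LPS vs control and 20 in LPS/LPS vs LPS, and leaving out LPS array 4 and LPS/LPS array 5 gave 0, 1 and 0. Calls at an unadjusted p put 213 genes in both LPS groups and 600 toward control. Lists past the threshold (16, 10 and 20) numbered 6, 0 and 8 with an estimated correlation and 7, 0 and 11 with fry. The 14 genes kept their direction wherever it was compared, with 11 of the 14 left by the filter. It was not compared in the 2-group fits, the other probe set choices or the fit without moderation. The lists past the threshold in all 21 settings in which lists were tested again were acute phase in LPS vs control, and interferon, metallothionein and unfolded protein genes in both LPS vs control and LPS/LPS vs LPS. MHC class I genes joined them in LPS vs control, and NRF2, proteasome and translation genes in LPS/LPS vs LPS. No detection calls were made, so changes of genes near the background are uncertain.

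Leaving out 1 replicate at a time gave ranges of 0 to 24 genes in LPS vs control (24 without LPS replicate 1, 5 without LPS replicate 3, 3 without LPS/LPS replicate 1, 1 without control replicate 4 or LPS/LPS replicate 5). In LPS/LPS vs control the range was 0 to 3 (3 without control replicate 3, 0 without control replicate 1 or 4 or LPS/LPS replicate 3). In LPS/LPS vs LPS it was 5 to 96 (96 without LPS replicate 1, 5 without LPS/LPS replicate 2, 3 or 5, 6 without control replicate 4 or LPS replicate 4, 7 without control replicate 3 or LPS/LPS replicate 4). Among the 3 groups it was 1 to 39 (39 without LPS replicate 1, 1 without LPS replicate 4, 2 without LPS/LPS replicate 3, 3 without control replicate 1 or 2, 4 without control replicate 4 or LPS replicate 2, 6 without LPS replicate 3 or LPS/LPS replicate 2 or 4, 8 without control replicate 3 or LPS/LPS replicate 1 or 5). Genes toward control ranged from 0 to 19 (19 without LPS replicate 1, 4 without LPS replicate 3, 2 without LPS/LPS replicate 1, 1 without control replicate 4). Lists ranged from 7 to 23, 3 to 13 and 18 to 23, with 7 without LPS replicate 3 and 3 without control replicate 1. The mean in LPS vs control ranged from -0.17 to 0.40 for oxidative phosphorylation and from -0.028 to 0.35 for the tricarboxylic acid cycle, lowest without LPS replicate 3 and highest without LPS replicate 1.

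With replicate numbers as a block, 3, 0 and 4 genes were called, 2 among the 3 groups and 2 toward control. The labels give no pairing, and residual correlations of arrays with the same number ranged from -0.351 to 0.215.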

Other observations

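The lists of nuclear RNAs and of further PPAR-alpha targets in this part were put together only after the results that prompted them were seen, and the test of nuclear RNAs against control after the others. Xdh, which encodes the uric acid forming xanthine dehydrogenase, and the lipase inhibitor gene Angptl4 differed by 1.54 (SE 0.25, limma adjusted p = 0.0597) and 1.03 (SE 0.17, adjusted p = 0.0688) in LPS vs control. In LPS/LPS vs LPS they differed by -1.26 (adjusted p = 0.0897) and -0.62 (adjusted p = 0.291). Neither passed the threshold, and both were chosen after their values were seen.

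Lists not described so far did not pass in any comparison. In LPS/LPS vs LPS the cell death list had a mean of 0.00 (adjusted p = 0.759), with the survival genes Bcl2l1 (-0.64) and Cflar (-0.62) lower adjusted over the list alone. The same held for 1 member each of NADPH oxidases and nitric oxide synthases (Xdh, list mean -0.05, adjusted p = 0.74), NAD and arginine metabolism (Sat1 -1.37, list mean -0.06, adjusted p = 0.731) and the integrated stress response (Slc3a2 -0.63, list mean -0.11, adjusted p = 0.118). Tight junction genes (-0.12, adjusted p = 0.118), glycolysis (-0.07, adjusted p = 0.255), sterol synthesis (-0.03, adjusted p = 0.434), heat shock (-0.03, adjusted p = 0.55), cell cycle (0.07, adjusted p = 0.402), clock genes (0.01, adjusted p = 0.731), cytokines (0.06, adjusted p = 0.662) and LPS sensing (-0.04, adjusted p = 0.658) had no member past the threshold adjusted over the list alone, except Cd14 in the last. For the cell death and clock lists the test pointed down while mean and median were positive.

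The fall of Malat1 in LPS/LPS vs LPS might reflect less nuclear RNA in the LPS/LPS arrays and not regulation of that gene. Other nuclear-retained and host-gene RNAs, 19 measured, had a mean of -0.22 in LPS/LPS vs LPS (limma camera, unadjusted p = 0.00184), with Neat1 at -1.19. Against control, where Malat1 differed by -1.50, their mean in LPS/LPS was -0.03 with a median of 0.08 (limma camera, unadjusted p = 0.619), which goes against less nuclear RNA in the LPS/LPS arrays than in control, and in LPS vs control it was 0.19 (limma camera, unadjusted p = 0.00783). Only 2 of the 19 had a mean above the background reference, so the explanation stays open. Counting nuclei per sample and measuring Malat1 against a nuclear small RNA would test it.

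Plin2, Pdk4 and Angptl4, among the lowest p in LPS vs control, are targets of the fatty acid receptor PPAR-alpha, so a PPAR-alpha target response to fatty acids may lie behind them. Other targets, 30 measured, had a mean of 0.12 in LPS vs control (limma camera, unadjusted p = 0.117), which leaves the PPAR-alpha target response open. In LPS/LPS vs LPS their mean was -0.20 (limma camera, unadjusted p = 0.00763, and p = 0.0757 with an estimated correlation). Chromatin binding of PPAR-alpha, or LPS given to mice without the receptor, would test it.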
